A study of Homo sapiens with 12 samples.

How the data were processed

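Poly(A)-selected RNA-seq was examined in 12 human cell line libraries, in 4 groups of 3. Hep3B and HepG2 are established lines derived from human liver tumours. Libraries labelled Hep3B carried a tetracycline-inducible control shRNA or an shRNA against CD146, the cell adhesion molecule encoded by MCAM. HepG2 libraries carried the pLVX vector or the vector with CD146. Groups were taken from the treatment labels. The titles number the shRNA libraries 1 to 3 in each group, which might denote different hairpins, but the treatment label is identical within each group and they were treated as replicates. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

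Raw counts per Ensembl gene ID were deposited by the authors, and no normalisation of these counts was found in the values, which were whole numbers with a different total in each library. FPKM values, scaled by gene length and library size, were also deposited by the authors, rounded to 2 decimals. Over 63032 values with at least 500 counts, the FPKM were proportional to the counts within each gene to within 0.147%. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.2.1 and HTSeq 0.6.1. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies may therefore have been split or lost. Of the 289 genes that the naming rule chose, 94 overlap another counted gene in the annotation, and their values are uncertain in this respect whether or not the overlap is given beside them.

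The table held 61806 gene IDs, of which 22258 had 0 counts in all libraries. Gene names were found for 61757 of the IDs, and 49 stayed without a name. Biotypes, gene positions and 3' UTR sequences were taken from GENCODE version 29 (GRCh38), which may differ from the annotation the authors used. Totals were between 12.8M and 18.1M counts per library (M, 1e6). A count of 3, used as the floor of detection, was worth between 0.165 and 0.235 CPM. The floor covers counting error only, as reads without molecular identifiers are not independent molecules, and the 95% interval given for a median of genes was a bootstrap over the genes (2000 resamples), which measures the spread between genes. Within groups, pairs of replicates differed by more than sampling noise (chi-square per gene between 1.74 and 3.93), so no library was counted as a copy of another.

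Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on the deposited counts, with TMM scaling and filterByExpr. Each line was fitted alone, p-values were 2-sided with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. Levels are given as CPM, counts scaled to a TMM-adjusted library total of 1e6 within each line, as mean ± SD of 3 libraries. The levels of CGA and those compared between the lines (the hepatocyte genes against 10 CPM and in the figure of liver transcripts, and CPS1, KRT7, VIM and CDKN2A over 6 libraries) were computed on unscaled totals, so that CPS1 and VIM differ slightly from their TMM-scaled levels. Fold changes are treated minus control on the log2 scale. The standard error (SE) was the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. For 38 gene lists, camera of limma 3.58.1 was run with a preset correlation of 0.01 between genes, again with a correlation estimated from the residuals, and beside fry. Adjusted p-values given for lists are from camera, Benjamini-Hochberg adjusted over the 38 lists. Calls of list members were counted over all genes tested and adjusted over the list alone.

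The responses of the lines were compared by Fisher's exact test on the overlap of calls, by correlation across genes, and by an edgeR contrast in a fit of all 12 libraries, in which the effect of higher CD146 in libraries labelled Hep3B (control minus CD146 shRNA) was subtracted from that in HepG2 (overexpression minus pLVX). Line and method of perturbation were confounded in this contrast.

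The groups, the tests, the 38 gene lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule named MCAM, the 12 largest rises and 12 largest falls per comparison among called genes with separate groups and at least 5 CPM in the higher group, up to 4 members with the smallest adjusted p from each list that was called or had at least 3 called members, up to 10 genes called in opposite directions and 5 in the same direction in both lines, and the 10 smallest adjusted p-values of the difference between lines. Clone-based, antisense, noncoding and pseudogene names were left out of the largest changes. Some genes that the rule names or that were examined otherwise are not reported here. Features named outside this rule are said to have been chosen after their values were seen.

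The alternatives were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) for genes of at least 1 FPKM, a replicate block, a fit of all 12 libraries, a threshold of 2-fold, other list tests, and each library left out in turn. Other pseudocounts for the FPKM were not run, as counts were used. Alternatives without mitochondrially encoded genes, without chromosome 11 and without genes holding an enriched 3' UTR 7-mer were added after the data were seen. Other splits of the 6 libraries of each line were refitted, 10 per line, 100 pairs of splits for the correlation and 40 drawn splits for the difference between lines.

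Enrichment of 7-mers was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, by regressing the log2 fold change on the presence of each 7-mer in the longest annotated 3' UTR, after UTR length, base and dinucleotide content, over 10964 genes of at least 3 CPM. Neighbouring genes of at least 5 CPM were examined in windows of 15 genes, and also of 5 and 9, against 200 shuffles of the gene order. Medians of windows, stretches and blocks, and of the neighbours of MCAM, are of log2 fold changes centred on the median of the genes of at least 5 CPM in each line. In libraries labelled Hep3B this centring moved MCAM from -2.25 to -2.19. The gene test was tested on simulated data with 200 changed genes, 50 at each fold. The changed genes were drawn from those of at least 2 CPM, so recovery at lower levels was not shown. With 16692 genes at the depth of the libraries labelled Hep3B, edgeR recovered 60% of genes changed 1.25-fold, 86% at 1.5-fold and 100% at 2-fold and 4-fold, with 4.42% false calls. With 15098 genes at the depth of HepG2, it recovered 62%, 84%, 98% and 100%, with 2.27% false calls. Camera found the planted list in both simulations with 0 false calls. The genes were simulated independently of each other, so the simulation could not show false calls of lists whose members are correlated. Reads were not used here, and the sequence of the hairpins was not given in the sources used here.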

Results

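Transcript levels were measured by RNA-seq after CD146 was lowered in libraries labelled Hep3B and raised in HepG2. Each of the 4 groups had 3 libraries. Totals were 13.8M to 16.7M counts with the control shRNA, 14.1M to 18.1M with the CD146 shRNA, 12.8M to 16.7M with pLVX and 13.3M to 16.9M with CD146 overexpression. Between 24377 and 28844 genes had a count in a library.

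MCAM (ENSG00000076706), the gene of CD146, lies on the minus strand of chromosome 11 from 119308529 to 119321521 in GRCh38 and overlaps CBL in the annotation. In libraries labelled Hep3B, MCAM stood at 114, 112 and 119 CPM with the control shRNA and at 22.0, 24.2 and 26.9 CPM with the CD146 shRNA. The mean fell from 115 ± 3.53 to 24.4 ± 2.44 CPM (SD, n = 3), which was 21.1% of control (log2 fold change -2.25, SE 0.06, edgeR adjusted p = 5.5e-29). In HepG2, MCAM stood at 22.9, 23.5 and 23.7 CPM with pLVX and at 1946, 1954 and 1897 CPM with CD146 overexpression. The mean rose 82.6-fold, from 23.4 ± 0.407 to 1932 ± 30.9 CPM (log2 fold change 6.37, SE 0.04, edgeR adjusted p = 5.6e-67). The counts do not separate the introduced from the endogenous copy. In both lines the exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

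**Figure D1:**
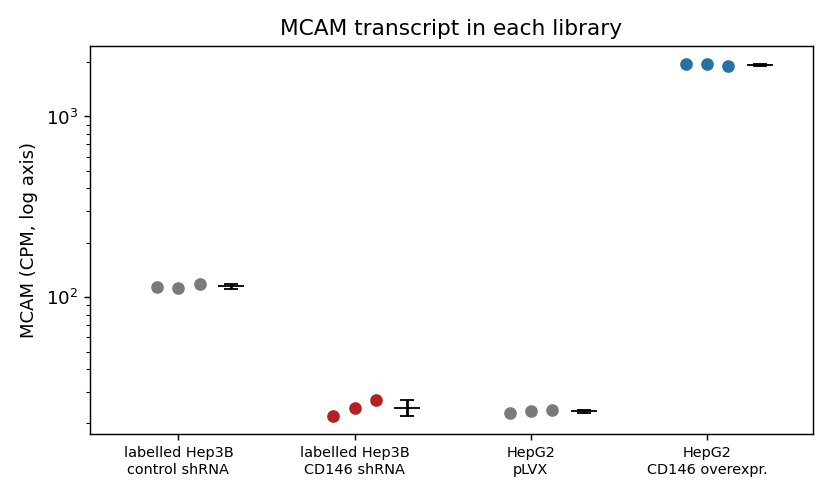
MCAM level in CPM (log axis) in each of the 12 libraries, by group, with points for libraries and bars for the group mean and SD. The CD146 shRNA libraries lie between 22.0 and 26.9 CPM against 112 to 119 CPM for their controls, and the overexpression libraries between 1897 and 1954 CPM against 22.9 to 23.7 CPM.

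The first comparison asked what changed when CD146 was lowered. With the CD146 shRNA, ANO2, a calcium-activated chloride channel, rose from 14.2 ± 0.682 to 256 ± 13 CPM (SD, n = 3; log2 fold change 4.17, SE 0.06, adjusted p = 2.7e-38). CDH5, the endothelial cadherin, rose from 0.754 ± 0.124 to 20.1 ± 0.792 CPM (log2 fold change 4.72), and CCN5, a matricellular protein, rose from 5.49 ± 0.240 to 42.1 ± 1.93 CPM (log2 fold change 2.94). LAMP1, a membrane protein of lysosomes, fell from 256 ± 9.76 to 40.7 ± 0.672 CPM (log2 fold change -2.65, SE 0.05, adjusted p = 3.1e-34). SLC38A5, an amino acid transporter, fell from 11.4 ± 1.71 to 0.447 ± 0.127 CPM (log2 fold change -4.64), and DTX4, a ubiquitin ligase, fell from 20.2 ± 1.85 to 2.31 ± 0.119 CPM (log2 fold change -3.13).

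Other large rises were those of TM4SF4 (2.99 on the log2 scale), SLC6A12, a betaine and GABA transporter (2.93), ALPK2 (3.29), the stress-induced cytokine GDF15 (3.11) and vitronectin (VTN, 3.11). VTN overlaps SARM1 in the annotation and is therefore uncertain. Other large falls were those of the sodium chloride cotransporter SLC12A3 (-3.00), ARPIN, an inhibitor of the Arp2/3 complex (-2.65), monoamine oxidase B (MAOB, -2.21) and PPP1R14C (-2.20). Some genes lay near the floor in one group, so their levels are given without a fold. COL1A2, a chain of type I collagen, stood at 0.191 ± 0.0224 and 6.16 ± 4.16 CPM, and its 3 treated libraries spread from 1.37 to 8.90 CPM. PSG9 stood at 0.142 ± 0.187 and 8.18 ± 1.41 CPM and PSG4 rose from 0.357 ± 0.0581 to 17.4 ± 1.71 CPM. The cancer-testis genes CSAG1 and MAGEA12 stood at 8.78 ± 0.954 and 0.0623 ± 0.00887 CPM and at 10.4 ± 0.304 and 0.0992 ± 0.0582 CPM. PSG and MAGEA genes have near-identical copies, and their values are uncertain.

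LAMP1, ARPIN, HBE1, OR51E2 and MCAM carried in their 3' UTR at least 1 of the 7-mers that were enriched among genes that fell, as did 31.9% of all genes examined. OR51B4 and the embryonic globin HBE1 fell by 2.62 and 2.58 on the log2 scale, and OR51E2 rose (log2 fold change 3.66). These 3 genes lie between 1.75 and 8.91 Mb on chromosome 11, a stretch whose 38 genes of at least 5 CPM had a median centred log2 fold change of -0.76, with 32 of them lower. OR51B4 overlaps HBE1 in the annotation, so both are uncertain.

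In all, 9385 of 16968 genes changed, 4555 upward and 4830 downward, with a median absolute log2 fold change of 0.43. At least 2-fold changes were found for 1362 genes, 1019 upward and 343 downward. Among 10963 genes of at least 3 CPM with an annotated 3' UTR, MCAM left out, 262 rose and 181 fell at least 2-fold. Most of the 1019 rises therefore lay among weaker genes or genes without such a UTR. The 3 values of one group lay all above those of the other for 59.8% of genes, where chance gives 10%. The spread between replicates was small, with a biological coefficient of variation of 3.79%.

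By camera with the preset correlation, 12 of the 38 gene lists moved, 7 upward and 5 downward, and 0 did so with an estimated correlation. All 14 genes of the heat shock list fell (14 also when adjusted over the list alone; median log2 fold change -0.63, adjusted p = 1.4e-17, and adjusted p = 0.261 with an estimated correlation). Among them HSPA8, the constitutive HSP70, fell from 1441 ± 68.5 to 782 ± 90.6 CPM, DNAJA1 fell from 247 ± 5.43 to 144 ± 12.7 CPM, and CHORDC1 fell from 165 ± 0.910 to 56.5 ± 1.83 CPM. CHORDC1 lies in a falling stretch of chromosome 11, and CHORDC1 and DNAJA1 carried an enriched 7-mer. HSPA1A fell by 1.18 on the log2 scale, but has a near-identical copy and is uncertain.

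Of 20 genes of endoplasmic reticulum chaperones and the unfolded protein response, 18 rose, 0 fell and 2 were not called (19 rose when adjusted over the list alone; median 0.63, adjusted p = 1.8e-16, and adjusted p = 0.274 with an estimated correlation). HYOU1 rose from 231 ± 12.8 to 487 ± 30.2 CPM, PDIA6, which overlaps ATP6V1C2, from 457 ± 16 to 808 ± 44.7 CPM and the stress sensor ERN1, which carried an enriched 7-mer, from 46.1 ± 1.53 to 88.7 ± 5.59 CPM. Of 24 cholesterol synthesis genes, 22 rose and 2 fell, with the same counts adjusted over the list alone (median 0.57, adjusted p = 2.6e-14, and adjusted p = 0.261 with an estimated correlation). MSMO1, a sterol oxidase that carried an enriched 7-mer, rose from 109 ± 3.14 to 218 ± 7.60 CPM, and SQLE rose from 162 ± 7.09 to 307 ± 17.9 CPM.

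Of 26 genes of G2/M and mitosis, 24 fell and 1 rose, with the same counts adjusted over the list alone (median -0.36, adjusted p = 7.8e-09, and adjusted p = 0.261 with an estimated correlation). CDK1 fell from 296 ± 9.86 to 175 ± 10.1 CPM, PLK1, which overlaps ERN2, fell from 110.4 ± 4.32 to 66 ± 2.67 CPM and CCNB1 fell from 213 ± 6.24 to 143 ± 4.27 CPM. Of 11 replication-dependent histone genes, 8 fell and 0 rose (9 fell when adjusted over the list alone; median -0.93, adjusted p = 5.6e-03, and adjusted p = 0.261 with an estimated correlation). These mRNAs lack a poly(A) tail and are multicopy, so their values, as for H2AC6 (15 ± 1.32 and 4.97 ± 0.795 CPM), are uncertain.

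Of 22 YAP/TAZ target genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.28, adjusted p = 4.1e-04, and adjusted p = 0.274 with an estimated correlation). CCN2 rose from 30.9 ± 3.45 to 126 ± 10.0 CPM and CCN1 rose from 55.2 ± 6.43 to 123 ± 10.6 CPM although it carried an enriched 7-mer, whereas AMOTL1, which lies in a falling stretch of chromosome 11 and carried an enriched 7-mer, fell by 1.29 on the log2 scale. Of 9 measured genes of the urea cycle and amino acid catabolism, 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.20, adjusted p = 4.5e-04, and adjusted p = 0.261 with an estimated correlation). CPS1 rose from 1609 ± 37.5 to 2991 ± 79.2 CPM and HPD from 63.2 ± 3.15 to 173 ± 3.88 CPM. Of 9 acute phase genes, 3 rose and 1 fell, with the same counts adjusted over the list alone (median 0.33, adjusted p = 0.035, and adjusted p = 0.274 with an estimated correlation). Complement C3, which overlaps GPR108, rose from 67.6 ± 2.15 to 158 ± 2.84 CPM. Of 14 MHC class I presentation genes, 7 rose and 0 fell, with the same counts adjusted over the list alone (median 0.20, adjusted p = 0.034, and adjusted p = 0.497 with an estimated correlation). B2M rose from 692 ± 11.2 to 909.7 ± 25.2 CPM, and the HLA genes, such as HLA-B (log2 fold change 0.77), are uncertain because of their similarity.

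Of 30 cytosolic ribosomal protein genes, 28 fell and 0 rose, with the same counts adjusted over the list alone (median -0.26, adjusted p = 8.6e-07, and adjusted p = 0.562 with an estimated correlation). Of 27 nuclear genes of the respiratory chain, 20 fell and 1 rose (21 and 1 adjusted over the list alone; median -0.24, adjusted p = 4.5e-04, and adjusted p = 0.562 with an estimated correlation). RPL13, which carried an enriched 7-mer, fell from 409.6 ± 33.2 to 257 ± 6.73 CPM, and NDUFS3, which overlaps PTPMT1 and 2 other genes, fell from 71.4 ± 3.34 to 44 ± 1.04 CPM. Of 13 mitochondrially encoded mRNAs, 10 rose and 0 fell (11 rose when adjusted over the list alone; median 0.29, adjusted p = 4.1e-04, and adjusted p = 0.497 with an estimated correlation). Mitochondrially encoded genes took 7.85 ± 0.157% of counts with the control shRNA and 9.90 ± 0.532% with the CD146 shRNA.

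Of 19 measured p53 targets, which camera did not call as a list, 7 rose and 5 fell (adjusted p = 0.532). Of 18 mesenchymal genes, 7 rose and 7 fell (7 and 8 adjusted over the list alone; adjusted p = 0.785; median -0.15, mean 0.27). FN1 rose from 4.21 ± 0.801 to 14.8 ± 4.47 CPM and vimentin (VIM) fell from 530.3 ± 4.79 to 379 ± 1.48 CPM. Of 24 integrin and focal adhesion genes, 11 rose and 7 fell (adjusted p = 0.540). ITGB1 rose from 657 ± 43.1 to 941 ± 16.6 CPM. PDK4, a kinase that restrains pyruvate oxidation, rose from 441 ± 12.3 to 1344 ± 9.73 CPM in the list of fatty acid oxidation, in which 5 of 18 genes rose and 8 fell (adjusted p = 0.540).

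No list of cell type markers was called. Only 7 of the 28 hepatocyte genes passed the filter in libraries labelled Hep3B, of which 1 rose and 2 fell (adjusted p = 0.845; median -0.22, mean 0.06). Of the cholangiocyte markers 2 of 9 rose and 3 fell (adjusted p = 0.692). Of the endothelial markers 2 of 6 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.0964). Of the fibroblast and stellate markers 3 of 6 rose and 0 fell (adjusted p = 0.0894). Of the leukocyte markers 1 of 4 rose and 0 fell (adjusted p = 0.845).

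None of the 28 hepatocyte genes reached a mean of 10 CPM in the 6 libraries labelled Hep3B, whereas 27 did in the 6 HepG2 libraries. Albumin (ALB) had 0 to 5 counts in 5 of the libraries labelled Hep3B and 298 in CD146 shRNA replicate 3, against 208167 to 349520 in HepG2. In CD146 shRNA replicate 3, 62 genes high in HepG2 and near 0 in the other libraries of its line held 580 counts, 0.110% of their HepG2 level. Genes chosen in the same way for each of the other libraries labelled Hep3B numbered 29 to 31 and held 9 to 21 counts, 0.0125 to 0.0281% of their HepG2 level.

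**Figure D2:**
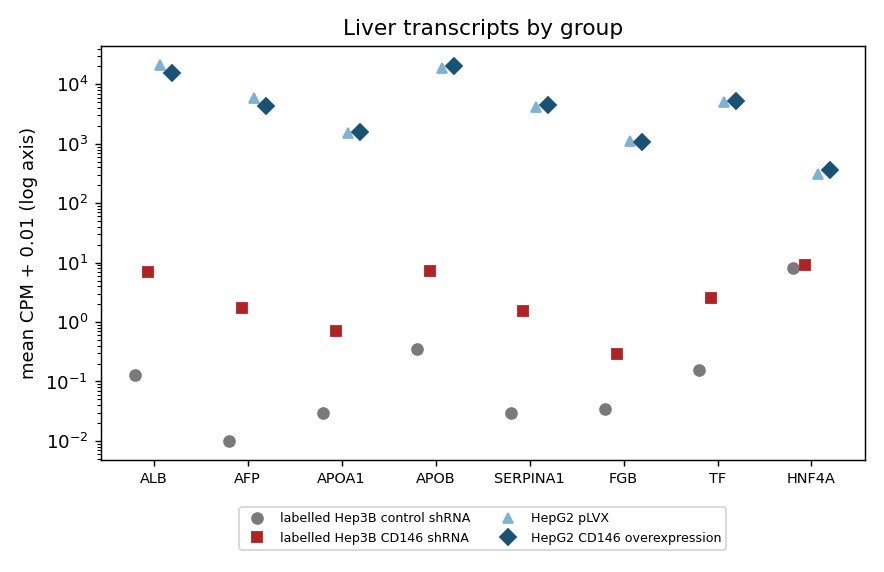
Mean level of 8 liver transcripts in CPM (plus 0.01, log axis) in each of the 4 groups of 3 libraries. The liver transcripts lie under 10 CPM in both groups labelled Hep3B, and the squares of the CD146 shRNA group include the 298 albumin counts of its replicate 3.

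**Figure D3:**
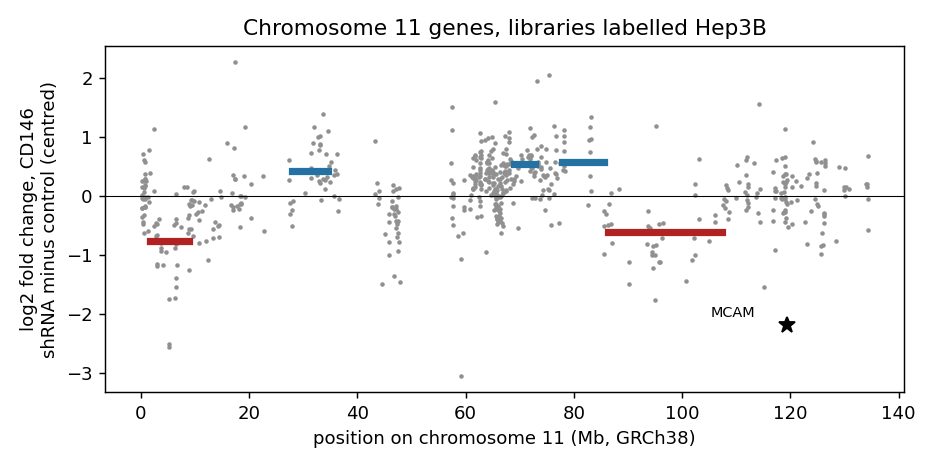
Log2 fold change of genes on chromosome 11 (centred on the median of genes of at least 5 CPM) by position in Mb in libraries labelled Hep3B, with a point for each gene, bars for the medians of stretches of neighbouring genes that moved together and a star for MCAM. The stretches at 1.75 to 8.91 Mb and 86.3 to 107 Mb have medians of -0.76 and -0.61.

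The second comparison asked what changed when CD146 was raised in HepG2. DKK1, a secreted inhibitor of Wnt signalling, rose from 11 ± 0.672 to 58.9 ± 3.04 CPM (SD, n = 3; log2 fold change 2.42, SE 0.07, adjusted p = 2.2e-33). The EGF receptor ligands AREG and EREG rose from 3.54 ± 0.169 to 15.4 ± 0.341 CPM and from 0.917 ± 0.327 to 5.11 ± 0.649 CPM, and the amino acid transporter SLC6A14 rose from 1.27 ± 0.524 to 12.7 ± 0.360 CPM (log2 fold change 3.25). FAM20A, a pseudokinase of the secretory pathway, fell from 19 ± 0.784 to 3.18 ± 0.130 CPM (log2 fold change -2.58, SE 0.12, adjusted p = 1.4e-24), and PTPRJ, a receptor tyrosine phosphatase, fell from 22.2 ± 1.00 to 4.16 ± 0.901 CPM (log2 fold change -2.39). FAM20A overlaps PRKAR1A in the annotation and is uncertain.

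Other large rises were those of CCDC170 (2.82 on the log2 scale), the desmosomal cadherin DSC3 (2.72), netrin 4 (NTN4, 2.01), the laminin chain LAMA3 (2.01), the interferon-inducible GTPase GBP1 (1.99), BAZ2B (1.97) and the peptide-amidating enzyme PAM (1.80). Other large falls were those of BAAT, which conjugates bile acids (-1.47), plasminogen (PLG, -1.41) and the glucose-6-phosphatase G6PC1 (-1.28). TNFSF4 (-1.38), PTPRN2 (-1.32), SLC16A6 (-1.23), SERPINA12 (-1.08), DLK1 (-1.08), LGALS2 (-0.97) and TEX19 (-0.96) fell as well.

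In all, 3037 of 15300 genes changed, 1461 upward and 1576 downward, with a median absolute log2 fold change of 0.25. At least 2-fold changes were found for 255 genes, 190 upward and 65 downward. The groups did not overlap for 33.6% of genes, where chance gives 10%. DESeq2 called 1614 genes, and limma on the FPKM called 1721, of which 75.5% were higher against 48.1% of the edgeR calls.

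By camera with the preset correlation, 22 of the 38 lists moved, 9 upward and 13 downward, and 6 also did so with an estimated correlation. Of 20 p53 target genes, 18 rose and 0 fell (20 rose when adjusted over the list alone; median 0.45, adjusted p = 5.3e-24, and adjusted p = 0.0157 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 25.3 ± 1.66 to 43.6 ± 1.96 CPM, MDM2 rose from 404 ± 5.52 to 564 ± 14.9 CPM and GDF15 rose from 63.1 ± 1.23 to 97.3 ± 4.51 CPM. Of 26 genes of G2/M and mitosis, 22 fell and 0 rose (24 fell when adjusted over the list alone; median -0.21, adjusted p = 8.1e-13, and adjusted p = 0.0214 with an estimated correlation). TOP2A fell from 1072 ± 17.1 to 855 ± 7.73 CPM and MKI67 from 514 ± 4.70 to 440.5 ± 13 CPM.

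Of 23 cholesterol synthesis genes, 15 fell and 0 rose (19 fell when adjusted over the list alone; median -0.17, adjusted p = 1.5e-13, and adjusted p = 0.0444 with an estimated correlation). FDFT1 fell from 357 ± 10.0 to 272 ± 5.00 CPM and HMGCS1 from 581 ± 5.97 to 468 ± 12.6 CPM. Of 19 fatty acid synthesis genes, 10 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.14, adjusted p = 1.8e-07, and adjusted p = 0.0444 with an estimated correlation). The desaturase SCD fell from 2397 ± 68.9 to 1695 ± 17.3 CPM. Of 8 cholangiocyte markers, 5 rose and 0 fell, with the same counts adjusted over the list alone (median 0.20, adjusted p = 2.8e-10, and adjusted p = 0.0444 with an estimated correlation). KRT19 rose from 27.5 ± 0.974 to 71.7 ± 5.24 CPM and EPCAM from 164 ± 3.52 to 212 ± 6.02 CPM. Of 22 genes of ATF4 and the integrated stress response, 11 rose and 0 fell (14 rose and 2 fell when adjusted over the list alone; median 0.16, adjusted p = 1.6e-07, and adjusted p = 0.0444 with an estimated correlation). ATF3 rose from 4.26 ± 0.391 to 11.7 ± 0.997 CPM and DDIT4 from 36.5 ± 0.920 to 62.9 ± 1.99 CPM.

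The other calls of camera were lost with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 12 fell and 0 rose, with the same counts adjusted over the list alone (median -0.31, adjusted p = 2.9e-23, and adjusted p = 0.0687 with an estimated correlation), while their genes took 12.7 ± 0.220% of counts with pLVX and 11.5 ± 0.292% with overexpression. Of 24 genes of G1/S and DNA replication, 20 fell and 0 rose (21 fell when adjusted over the list alone; adjusted p = 5.5e-09, and adjusted p = 0.0885 with an estimated correlation). MCM3 fell from 389 ± 3.71 to 334 ± 5.50 CPM. Of 27 nuclear genes of the respiratory chain, 17 fell and 0 rose (21 fell when adjusted over the list alone; adjusted p = 8.1e-08, and adjusted p = 0.124 with an estimated correlation). Of 28 hepatocyte genes, 11 fell and 5 rose, with the same counts adjusted over the list alone (median -0.02, adjusted p = 2.7e-06, and adjusted p = 0.0687 with an estimated correlation). Albumin (ALB) fell from 21987 ± 543 to 15150.0 ± 239 CPM, and AFP fell by 0.53 on the log2 scale.

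Of 17 hypoxia-induced genes, 9 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 8.0e-04, and adjusted p = 0.223 with an estimated correlation). Of 14 NF-kB-induced genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 1.3e-03, and adjusted p = 0.0840 with an estimated correlation). IRF1 rose from 5.99 ± 0.448 to 9.48 ± 0.0501 CPM. Of 21 ERK output genes, 7 rose and 4 fell (8 and 5 adjusted over the list alone; adjusted p = 3.5e-03, and adjusted p = 0.291 with an estimated correlation). JUN rose from 15.1 ± 1.70 to 36.6 ± 2.61 CPM. Of 18 epithelial junction genes, 7 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 1.9e-03, and adjusted p = 0.124 with an estimated correlation). CLDN1 rose from 179 ± 3.55 to 248 ± 12.7 CPM. Of 25 interferon-induced genes, 8 rose and 1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0302, and adjusted p = 0.152 with an estimated correlation). This call was lost without overexpression replicate 2 (adjusted p = 0.0583). Of 6 fibroblast and stellate markers, 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.0404, and adjusted p = 0.223 with an estimated correlation). This call was lost without pLVX replicate 3 (adjusted p = 0.177), overexpression replicate 1 (0.113) or overexpression replicate 2 (0.197), without chromosome 11 (0.151) and without a filter (0.219), where the median of 0.50 became -0.13.

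Of 24 NRF2 target genes, 11 fell and 5 rose (12 and 6 adjusted over the list alone; adjusted p = 2.0e-03, and adjusted p = 0.152 with an estimated correlation). Of 19 fatty acid oxidation genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 2.0e-03, and adjusted p = 0.303 with an estimated correlation). FABP1 fell from 303 ± 9.27 to 194 ± 5.51 CPM. Of 18 genes of the urea cycle and amino acid catabolism, 6 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 7.5e-03, and adjusted p = 0.152 with an estimated correlation). Of 16 acute phase genes, 7 fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 7.6e-03, and adjusted p = 0.166 with an estimated correlation). C3 fell from 4099.7 ± 108 to 3406 ± 81.6 CPM. Of 22 glycolysis genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0117, and adjusted p = 0.303 with an estimated correlation). The glucose transporter SLC2A1 fell from 251 ± 2.31 to 145 ± 0.998 CPM. Of 30 ribosomal protein genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.05, adjusted p = 3.1e-03, and adjusted p = 0.537 with an estimated correlation). This call was lost without overexpression replicate 1 (camera adjusted p = 0.0837) and with fry (fry adjusted p = 0.106).

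Of the lists called in libraries labelled Hep3B, heat shock genes (1 of 14 rose and 2 fell, adjusted p = 0.291), unfolded protein response genes (2 of 20 rose and 5 fell, 2 and 7 adjusted over the list alone, adjusted p = 0.446) and YAP/TAZ targets (7 of 18 rose and 3 fell, 8 and 3 adjusted over the list alone, adjusted p = 0.0892) were not called in HepG2. Nor were MHC class I genes (0 of 14 rose and 3 fell, adjusted p = 0.247) and replication-dependent histone genes (1 of 6 rose and 0 fell, adjusted p = 0.446). The endothelial markers (0 of 5 rose and 2 fell, adjusted p = 0.148) and the leukocyte markers (0 of 6 rose and 1 fell, adjusted p = 0.0557) were not called either.

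**Figure D4:**
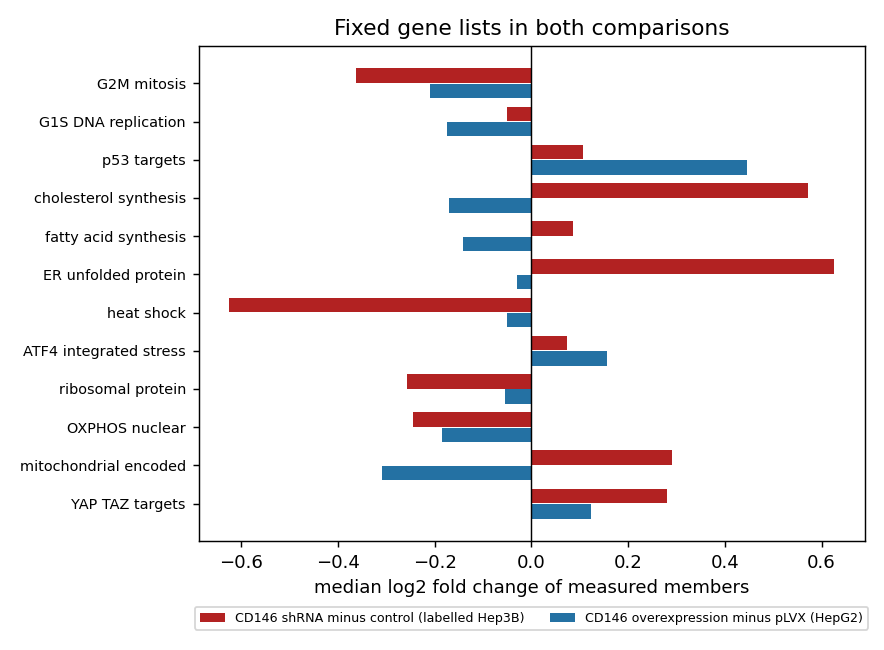
Median log2 fold change of the measured members of 12 gene lists, with bars for the CD146 shRNA minus control in libraries labelled Hep3B and for overexpression minus pLVX in HepG2. Heat shock genes lie at -0.63 in libraries labelled Hep3B, and p53 targets at 0.45 in HepG2.

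The third comparison asked whether the same genes followed CD146 in both lines. SLC16A6, a transporter of the monocarboxylate family, rose with the CD146 shRNA (log2 fold change 2.23) and fell with overexpression (log2 fold change -1.23). The transcription factor SOX4 fell (-1.41) and rose (1.14), as did FBLIM1 (-0.97 and 1.27), KITLG, the ligand of KIT (-0.78 and 1.04), MICAL2 (-0.83 and 0.72) and SH3BGRL (-0.84 and 0.71). BIRC3 (-1.06 and 1.18), ARHGAP42 (-1.51 and 0.90) and CEP126 (-1.14 and 0.76) did so too, and these 3 genes lie in the falling stretch of chromosome 11 from 86.3 to 107 Mb. TEX19 rose (1.24) and fell (-0.96). SOX4, FBLIM1, KITLG, MICAL2 and BIRC3 carried an enriched 7-mer, and SLC16A6 overlaps ARSG in the annotation and is uncertain.

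Other genes moved the same way in both lines. PTPRJ fell in both (-1.52 and -2.39) and carried an enriched 7-mer, and INHBE (1.86 and 0.98), ATF3 (0.98 and 1.44), FSTL3, in a rising stretch of chromosome 19 (1.04 and 0.91), and DKK1 (0.90 and 2.42) rose in both. Of 13559 genes tested in both lines, 1797 were called in both. Of these, 741 moved in opposite directions, where 755 were expected from independent calls, and 1056 moved in the same direction, where 765 were expected. Genes lower with the CD146 shRNA and higher with overexpression numbered 349 against 402 expected (Fisher's exact test, Benjamini-Hochberg adjusted over 4 tests, p = 8.9e-04), and genes higher and then lower 392 against 353 (p = 0.0112). Genes lower in both numbered 603 against 450 (p = 3.0e-19), and genes higher in both 453 against 316 (p = 3.0e-19), by the same exact test. Genes are not independent replicates, so these p-values do not measure the spread between libraries. Across genes, with the same limit, the log2 fold changes had a Pearson r of 0.0924 and a Spearman rho of 0.0898.

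The fourth comparison tested the difference of the effect of higher CD146 between the lines, which is confounded with the method of perturbation. By this test 6866 of 18870 genes differed, 3240 with the effect above in HepG2 and 3626 with it below. LAMP1 fell with the CD146 shRNA (-2.65) and stood at 198 ± 3.96 and 184 ± 3.45 CPM with pLVX and overexpression (difference -2.75, adjusted p = 1.8e-40). CEMIP2 rose with the CD146 shRNA from 346 ± 17 to 855 ± 27.5 CPM (difference 1.44), GDPD5 rose from 14.3 ± 1.08 to 56.7 ± 2.40 CPM (difference 2.03), CD59, an inhibitor of complement, rose from 353 ± 9.48 to 884 ± 19.2 CPM (difference 1.43), and TMEM245 fell from 432 ± 11.9 to 186 ± 1.63 CPM (difference -1.29). GDPD5, CD59, TMEM245 and COL4A5 carried an enriched 7-mer, and CD59 lies in a rising stretch of chromosome 11. AKAP12 rose in both lines, by 1.21 and 0.70 on the log2 scale (difference 1.91), as did the collagen chain COL4A5, by 0.49 and 1.43 (difference 1.92).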

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

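The tests of a difference between lines were planned, whereas the counts over other splits of the libraries and the levels at the floor were chosen only after the result was seen. The response to higher CD146 differed between HepG2 and the libraries labelled Hep3B for 6866 genes by the edgeR contrast, out of 18870 tested. It also differed for 220 of the 289 genes named by the fixed rule, a count that the rule itself raised, as it named genes for being called. Of 40 drawn splits of the libraries, 1 gave as many genes, the real one, and the highest of the others gave 4525. That highest other kept the real grouping of the libraries labelled Hep3B and changed that of HepG2 alone, and drawn splits that changed both groupings gave 0 genes. A large count can therefore come from the effect in the libraries labelled Hep3B alone. The splits cannot show that the effects differ between the lines.

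The difference, HepG2 minus libraries labelled Hep3B on the log2 scale, was 4.12 for MCAM, 3.33 for DKK1, 2.03 for GDPD5, 1.92 for COL4A5, 1.91 for AKAP12, 1.5 for HPD, 1.44 for CEMIP2 and 1.43 for CD59. It was -3.91 for PTPRJ, -2.75 for LAMP1 and -1.29 for TMEM245. MCAM fell by 2.25 and rose by 6.37, so its difference came from the larger step of the overexpression.

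Of the 38 gene lists, 4 differed between lines both with the preset and with an estimated correlation. Their median differences were -0.69 for heat shock genes, -0.58 for G2/M and mitosis, 0.65 for YAP/TAZ targets and 0.35 for p53 targets (adjusted p = 0.0391, 0.0073, 0.0391 and 0.0090 with an estimated correlation). The contrast reverses the shRNA effect, so lists that moved the same way with both treatments count as differing. With the CD146 shRNA and with overexpression the medians in this fit were -0.62 and -0.05 for heat shock genes and -0.36 and -0.21 for G2/M and mitosis. They were 0.28 and 0.13 for YAP/TAZ targets and 0.08 and 0.45 for p53 targets. The following differed only with the preset correlation, with adjusted p between 0.0581 and 0.473 with an estimated one. The median difference was 0.56 for the unfolded protein response, 0.41 for cholesterol synthesis, 0.33 for epithelial junctions, 0.48 for NF-kB-induced genes, 0.49 for interferon-induced genes, 0.21 for MHC class I, 0.18 for hypoxia, 0.12 for ATF4 and the integrated stress response, 0.23 for secreted angiogenic factors, 0.36 for stem cell-associated genes and 1.11 for fibroblast and stellate markers. It was -0.41 for nuclear genes of the respiratory chain, -0.32 for ribosomal proteins, -0.23 for G1/S and DNA replication and -0.17 for glycolysis. The fit of all 12 libraries kept list members that failed the filter in libraries labelled Hep3B. Stem cell-associated genes numbered 18 against 12 there, and their median with the CD146 shRNA was 0.36 against 0.06. Fibroblast and stellate markers numbered 8 against 6, with 0.77 against 0.47. NF-kB-induced genes numbered 17 against 14 in each line, and their median with the CD146 shRNA was 0.16 against 0.02. Members that failed the filter in HepG2 were kept as well, and YAP/TAZ targets numbered 22 against 18 there. The differences of these lists therefore rest partly on weakly counted genes.

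The hepatocyte list had a median difference of 2.39 and the list of the urea cycle and amino acid catabolism 0.44 (adjusted p = 0.606 and 0.209 with an estimated correlation), but several members lay at or under the floor in libraries labelled Hep3B, so these fitted medians are no bound. With group means raised to the floor of 3 counts and members at the floor in both groups left out, the hepatocyte median was 1.24 over 22 genes, and 0.13 over 11 genes without CD146 shRNA replicate 3. The median of the urea cycle and amino acid list was 0.67 over 14 genes, and 0.51 without that replicate.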

How the results depend on the processing

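The alternatives without mitochondrially encoded genes, without chromosome 11 and without genes holding an enriched 7-mer were chosen only after the result was seen. No called gene or list that was checked reversed its direction under any alternative run, although the median of the fibroblast and stellate markers in HepG2 went from 0.50 to -0.13 without a filter. With a threshold of 2-fold, 1362 genes were counted in libraries labelled Hep3B and 255 in HepG2. In HepG2, DESeq2 called 1614 genes and limma on the FPKM 1721, of which 75.5% were higher against 48.1% with edgeR. The cause was not tested. In libraries labelled Hep3B, DESeq2 called 7520 genes and limma on the FPKM 7572, of which 39.4% were higher against 48.5% with edgeR, and 58.4% of calls were higher with upper-quartile scaling. No scaling moved the median of all genes by over 0.1, but smaller shifts went with the changed shares of higher calls. In libraries labelled Hep3B the shift was 0.070 with upper-quartile scaling (58.4% higher) and -0.032 with the FPKM (39.4%). In HepG2 it was 0.066 with the FPKM (75.5%), where the median absolute log2 fold change of the edgeR calls was 0.25. With an estimated correlation camera called 0 lists in libraries labelled Hep3B and 6 in HepG2, and fry, which tests another hypothesis, called 30 in libraries labelled Hep3B and 29 in HepG2, against 12 and 22 in the main analysis. Correlation between members cannot account for every call that camera lost. The estimate was below the preset 0.01 for acute phase genes in libraries labelled Hep3B (-0.087) and for interferon-induced genes in HepG2 (-0.0061), and both calls were lost. Without a filter, 18 and 23 lists were called. Single results were checked once per alternative for the genes that the naming rule chose, without MCAM, and for the lists called in the main analysis. In these checks the outcome, called or not, was the same in 6367, a call was lost in 129 and gained in 15. Lists called only under an alternative are not among them.

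Of the genes called in both lines, 13 moved in opposite directions and 24 in the same direction at 2-fold in both, and 378 and 559 with DESeq2, as fewer genes passed. Without genes holding an enriched 7-mer, 473 moved in opposite directions, as fewer genes were tested. The correlation across genes was 0.0244 over genes of at least 10 CPM in both lines, 0.0742 with DESeq2, 0.106 without chromosome 11 and 0.107 without genes holding an enriched 7-mer, and between 0.0764 and 0.112 with 1 library left out. The cause was not tested.

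With 1 library left out, 8645 to 8894 genes were called in libraries labelled Hep3B and 2262 to 2675 in HepG2, and the log2 fold change of MCAM was between -2.32 and -2.17 and between 6.36 and 6.38. The counts called by limma-voom (9351 and 3000) and with the other scaling RLE (9374 and 3042) lay within 1.5 times those of edgeR.

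With the replicate number as a block, 9543 genes were called in libraries labelled Hep3B and 2947 in HepG2, of which 9358 and 2903 were among the calls without the block, and the block changed no count of calls by over 1.5 times. Whether equal numbers mark paired libraries was not settled by these values. Deviations of libraries with the same number correlated at 0.103, 0.0499 and 0.0313 in libraries labelled Hep3B and at -0.0418, -0.0439 and 0.0181 in HepG2. With different numbers the correlations lay between -0.106 and 0.065 in libraries labelled Hep3B and between -0.0509 and 0.0861 in HepG2. Not every library correlated best with its own number. Depth limited genes near 3 counts, for which no fold is given.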

Other observations

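The gene families and the tests of the 3 patterns were chosen only after the result was seen, except the tests of longer sites, of genes without a site and of weakly expressed genes in the blocks, which were written before their results. Metallothioneins, which bind zinc and copper, fell in both lines, 3 of 3 measured genes in libraries labelled Hep3B (median log2 fold change -1.5) and 7 of 7 in HepG2 (median -0.82). MT2A fell from 21.2 ± 1.01 to 7.41 ± 0.710 CPM with the CD146 shRNA and from 79.3 ± 8.19 to 43.6 ± 3.75 CPM with overexpression. These genes are similar in sequence and their values are uncertain. The 5 measured SPINK protease inhibitor genes rose with the CD146 shRNA (median 1.67), with SPINK5 rising from 47.3 ± 2.81 to 187 ± 1.64 CPM and SPINK13 from 54.4 ± 2.04 to 173 ± 8.80 CPM. CGA, the alpha subunit of glycoprotein hormones, rose from 384 ± 19.6 to 1568 ± 56.3 CPM of the unscaled totals.

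On chromosome 17, neighbours of SLC16A6 moved with it. With the CD146 shRNA, ARSG rose from 14.9 ± 0.297 to 26.1 ± 1.29 CPM and WIPI1 rose from 10.1 ± 1.03 to 18.9 ± 1.23 CPM, and with overexpression in HepG2 ARSG fell from 15 ± 1.35 to 9.69 ± 0.983 CPM, WIPI1 fell from 23 ± 2.44 to 16.2 ± 1.66 CPM and PRKAR1A fell from 363 ± 15.2 to 215 ± 6.65 CPM. Some of these genes overlap in the annotation, so their reads cannot be told apart.

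Of the 28 hepatocyte genes, 0 reached 10 CPM in the libraries labelled Hep3B, whereas the urea cycle gene CPS1 stood at 2286 ± 725 CPM there and at 98.6 ± 6.26 CPM in HepG2 (SD, n = 6), and of other genes chosen after their values were seen KRT7 stood at 117 ± 17.6 and 0.0657 ± 0.0386 CPM, VIM at 455 ± 89.0 and 2.05 ± 0.488 CPM and CDKN2A at 47.9 ± 5.53 and 0.839 ± 0.186 CPM. A loss by filtering or counting was excluded, as 27 of the 28 genes reached 10 CPM in HepG2 in the same table. A cell line other than Hep3B or Hep3B cells that lost liver expression stay open as candidate explanations of the 0 of 28 genes. These candidates were not told apart by the values given here. The counts of CD146 shRNA replicate 3 held one ratio to the HepG2 level over 62 genes (chi-square per gene 1.00, r across genes 0.985), which is consistent with a small share of reads from HepG2 libraries in that library.

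Genes with certain 7-mers in the 3' UTR lay slightly lower with the CD146 shRNA. Of 16189 7-mers tested, GGTGTTA had a standardised effect (the effect over its standard error) of -8.43, AGGTGTT -7.53, AGGTGTA -7.27 and CAGGTGT -7.00. The lowest 7-mer that did not overlap these had -4.04. On the log2 scale the 4 effects were small, at -0.133, -0.0981, -0.114 and -0.0835. The median log2 fold change was -0.16 over 332 genes with GGTGTTA and AGGTGTT joined and -0.049 over 7466 genes with none of the 4 (no site). Of these genes 52.1% and 36.3% fell. Among genes that fell at least 2-fold, 97 of 181 held a site, against 65 of 262 that rose (Fisher's exact 2-sided p = 7.5e-10). Of the 10963 genes examined, 3497 did (31.9%). As these 7-mers were picked from the same fold changes, that p-value is no independent support. UTR length and composition were not removed in this count. Seed pairing of the hairpin, an off-target effect, is a candidate explanation, as GGTGTTA and AGGTGTT overlap by 6 bases and the latter lies at 2 places in the MCAM transcript, both before the 3' UTR, CAGGTGT lies at 4, of which 2 are in the 3' UTR, and GGTGTTA and AGGTGTA lie at 0. UTR length and base composition were removed before the effect of -7.53 and so were excluded as its whole cause. Genes with both 7-mers joined had a median log2 fold change further down by -0.044 than genes with a single one, under the 0.1 set beforehand, so this test leaves the seed open. An endogenous microRNA that responds to CD146 stays open as well, as GGTGTTA had an effect of 0.131 in HepG2, where such a microRNA need not be present.

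Blocks of neighbouring genes on chromosome 11 moved together in libraries labelled Hep3B, down at 1.75 to 8.91 Mb and 86.3 to 107 Mb and up at 28 to 34.7, 68.9 to 72.8 and 77.9 to 85.7 Mb, and smaller blocks on chromosome 19 (15 genes, median 0.61) and chromosome 21 (20 genes, median 0.52), to which the tests of genes in blocks were not applied, moved up. Chance order was excluded, as the largest median was 1.00 in windows of 15 genes, 1.40 with 9 genes and 1.76 with 5 genes, and 0, 0 and 1 of 200 shuffles gave one as far from 0 with windows of the same size. The hairpin's sites were excluded as the whole cause, as the 46 genes of the falling blocks without a site had a median of -0.62. A copy-number difference between control and CD146 shRNA cells may account for the blocks, as genes at 1 to 5 CPM, which did not define them, had medians of -0.52 in the falling blocks (32 genes, 95% interval over genes -0.75 to -0.13) and 0.86 in the rising blocks (16 genes). A response to CD146 cannot be told apart, as these genes had a median of 0.024 in HepG2, where a response need not be shared.

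A further stretch, on chromosome 5 in libraries labelled Hep3B (18 genes, median 0.15), held 8 genes that were lower and 10 that were higher. In HepG2, windows of 15 genes gave no such block (61 of 200 shuffles were as large). Windows of 9 genes reached a median 0.596 below 0, as large in 1 of 200 shuffles, and windows of 5 genes 0.767 below 0, as large in 4 of 200. Both lay on chromosome 16, and their middle values were those of MT1X and MT1E, metallothioneins that fell. The 10 genes nearest to MCAM had a median centred log2 fold change of -0.11 in libraries labelled Hep3B and 0.15 in HepG2.

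With 3 libraries against 3, the 10 splits of each line are too few to exclude chance. In libraries labelled Hep3B the real split gave 9385 genes, and 1 of 10 splits was as large, with 0 genes in the highest other. It gave 12 lists, and 2 of 10 splits gave as many, the highest other giving 12. In HepG2 the real split gave 3037 genes with 0 in the highest other (1 of 10) and 22 lists with 11 in the highest other (1 of 10). For the correlation between lines, 6 of 100 pairs of splits were as far from 0 as the real one (0.0895, computed for the splits from group means of log2 CPM, against 0.0924 from the edgeR fits), the highest other being 0.0978, so chance was not excluded.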
